A study of Mus musculus with 27 samples.

How the data were processed

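The series measured chromatin-associated RNA, the RNA that stays bound to chromatin when nuclei are extracted and which is rich in nascent transcripts, in mouse embryonic stem (ES) cells from a 129S X Cast cross. The cells differ between their chromosome copies at many bases, so reads can be assigned to the 129S or the Cast allele. Per the labels, the Xist promoter on the 129S X chromosome was replaced by a doxycycline-inducible (TetOn) promoter, and a stem-loop array was placed at the Xist 3' end. Doxycycline was used at 1.0 to 1.5 µg/mL, per the labels' growth protocol. ES cells were grown on mitomycin-treated mouse fibroblast feeders, so some RNA of feeder cells can be present. Libraries were made with a stranded total RNA kit, per the labels' protocols.

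Per the labels, the groups are a parental line (WT), a CIZ1 knockout (CIZ1 KO), a line labelled SpenKO (named SpenRRM in the series text) and a line with a mutated Spen SPOC domain (SPOCmut), each without doxycycline (0 h) and after 24 h. WT and SpenKO were also sampled at 3 h, and WT and CIZ1 KO as neural precursor cells (NPC) at day 30. Most groups held 2 libraries, the SPOCmut groups 3, and SpenKO at 3 h and each NPC group 1. Whether the NPC cultures received doxycycline is not stated in the sources used here. Nothing in the labels says that replicate libraries came from separate cultures, except that the 3 SPOCmut replicates are separate clones. P-values therefore measure the spread between these libraries, which may be technical. The labels give several clones only for SPOCmut, so differences between lines can reflect the line as well as the genotype.

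The values deposited by the authors are allelic ratios, a fraction from 0 to 1 per gene and library, in 3 tables: 270 X-linked genes in 17 libraries (the Spen table), 254 X-linked genes in 10 libraries (the CIZ1 table) and 458 chromosome 15 genes in 8 libraries. The submitters' processing notes list Bowtie2 2.3.2, STAR 2.4.2a, featureCounts, SAMtools, bedtools and edgeR without roles, and the build mm10. The allele behind the numerator is not named in the sources used here. Xist lies near 1 in each library while the labels put the inducible Xist on 129S, so the ratio is read as the 129S share of allele-assigned reads. A fall after doxycycline is then a lower share of RNA from the X that carries the induced Xist. Without expression levels, a loss from this X cannot be told apart from a gain from the Cast X. The filters behind the gene lists of the tables, and the strand setting of the counting, are not given in the sources used here. Reads of Xist and its antisense gene Tsix can therefore not be told apart with certainty. Values of other overlapping genes, of multigene families (such as Xlr, Mageb and Rhox) and of genes with many processed copies (such as ribosomal protein genes and Slc25a5) are uncertain in the same way. The deposited fraction comes without read counts, so the depth of each library and gene is unknown and no interval from counting error is given. Each ratio is formed within a library, and no scaling between libraries was applied here.

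The 2 X tables share 248 genes and 4 libraries, and the shared values are identical. No value is missing. Replicate libraries shared at most 1.11% of exactly equal values, so none was treated as a copy. The chromosome 15 table is tied by the labels to a male line with an Xist transgene on chromosome 15, but its columns carry the names of the WT and SpenKO X lines. The 4 transgene samples therefore have no column, and their comparison, although planned, is not analysed here. The table was used as an autosomal control for the X lines instead, a use chosen after its columns were seen. Its 4 further columns are the authors' means of replicate columns, equal to the means to within 6e-16, and were not used. Columns marked Dox with no time were taken as 24 h, because the Spen table sets that name beside separate 3 h columns. Spen and Ciz1 are not among the genes of these tables, so the targeted genes were not checked.

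Each comparison was fitted with limma 3.58.1 in R 4.3.3 on the raw ratios, with all libraries of a table in 1 fit, no replicate block and Benjamini-Hochberg adjustment over the genes of that table. A gene was called at an adjusted p under 0.05. Changes are differences of group means with the standard error (SE) from limma. Differences between lines in their response to doxycycline were tested as interaction contrasts in the same fits. For the 3 h difference between SpenKO and WT, the lone SpenKO library is assumed to vary like the other groups. Medians over genes were compared between groups by exact two-sided permutation tests. The smallest p these allow is 0.333 for 2 against 2 libraries, 0.2 for 3 against 2 and 0.1 for 3 against 3, so none can pass 0.05. Groups of 1 library are described by their values, with no p for them alone.

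Fixed lists of 9 X-linked and 5 chromosome 15 gene groups were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation. The X lists are escape genes, the X inactivation centre and neighbours, chromatin and transcription regulators, RNA processing and translation, ubiquitin and proteolysis, metabolic and mitochondrial enzymes, pluripotency and early development, neural genes and feeder fibroblast genes. The chromosome 15 lists are chromatin and transcription regulators, RNA processing and translation, mitochondrial and metabolic enzymes, cell cycle with cytoskeleton and DNA repair, and feeder fibroblast genes. Of the 14 feeder fibroblast genes in the Spen table, 2 (Gpc3 and Gpc4) are also in the pluripotency list. How many of them the ES cells express themselves was not measured, because the tables hold no expression levels. Camera works on moderated statistics and not on the changes themselves. In several lists with no call its direction differed from that of the list's median. For the NPC libraries, a list's median was placed among 10000 random lists of the same size. These were not matched on expression or on position along the X.

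Change along the X was summarised in 20 Mb bins and by the Spearman correlation of the change with the distance to Xist over genes, with 100000 permutations. The smallest p these permutations can give is 1e-05. These 5 correlations were adjusted together. Genes are not independent replicates. A scan for 1 change point along the X was run on 4 profiles, after the NPC values had been seen.

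The groups, the comparisons between them with their tests, the gene lists, the rule for named genes and all alternatives but 5 were fixed before the data were examined. The rule for named genes took, per comparison, the 8 largest falls and 5 largest rises among called genes whose replicates do not overlap, and the 5 least changed genes with a no-doxycycline mean from 0.3 to 0.7 (for WT at 24 h). For differences between lines and for comparisons of 1 library it took the 6 largest in each direction. From each list it took up to 4 members with the smallest and 2 with the largest adjusted p, and it always took genes such as Xist, Tsix, Kdm6a, Eif2s3x, Ddx3x and Hprt. Some of these are left out for room, and a few genes the rule takes are not reported here. Any other gene named is said to have been chosen after its values were seen.

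Alternatives were a logit scale (values held within 0.01 and 0.99), an arcsine scale, only the groups compared in the fit, a filter on no-doxycycline means from 0.2 to 0.8, eBayes with trend and robust options, a minimum change of 0.1, Benjamini-Yekutieli adjustment, the replicate number as a block, leaving out each library in turn, 10 Mb bins, other NPC limits than 0.1, and other summaries over genes. The 5 alternatives added after the data were seen are the CIZ1 table for WT at 24 h, leaving out genes before 13 Mb for WT at 3 h and at 24 h, 10 Mb bins for the NPC difference, and leaving genes of the escape list out of other lists for the NPC libraries. The correlations with distance without genes before 13 Mb are not counted among these.

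The replicate numbers of the SPOCmut libraries pair them, since the titles give the same clone names (C10, C2 and G1) with and without doxycycline. Over genes, the deviations of the paired libraries from their group means correlated by -0.0170, -0.113 and 0.148.

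The fits were tested on simulated data built from the real spread, with 40 genes changed by each known size in each of 20 simulations. So many changed genes loosen the Benjamini-Hochberg cutoff, so the shares recovered would be lower where few genes differ. In the simulated comparison of WT at 24 h over 270 genes, 33.9% of falls of 0.05, 68.3% of falls of 0.1 and 88.3% of falls of 0.2 were recovered. For CIZ1 KO against WT at 24 h over 254 genes the shares were 23.3%, 57.4% and 86.3%. For the difference of the 24 h effects of these lines they were 4.0%, 28.8% and 68.9%. For SpenKO at 24 h they were 33.3%, 64.0% and 88.8%, and for WT over 458 genes of chromosome 15 they were 21.3%, 57.5% and 84.1%.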

Results

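Allelic ratios of chromatin-associated RNA were examined in 23 libraries of 12 groups of female ES cells and derived NPC, in which Xist can be induced with doxycycline from the 129S X chromosome. Xist is the long noncoding RNA that coats an X chromosome in cis and silences its genes. CIZ1 is a nuclear matrix protein known to bind Xist RNA, and SPEN is an Xist-binding repressor whose SPOC domain contacts corepressors. The series set out to compare Xist-mediated silencing in lines changed in these factors. The values are the 129S share of allele-assigned reads of a gene, so 0.5 means equal RNA from both X chromosomes. Values are means ± SD over libraries unless stated, changes are given with the SE from limma, and the depth of the libraries is unknown.

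Xist (chromosome X, 103460372 to 103483233, mm10) had a ratio from 0.933 to 0.999 over the 17 libraries of the Spen table, with or without doxycycline. Without doxycycline the per-library median over X genes was 0.509 ± 0.00661 in WT, 0.515 ± 0.00505 in SpenKO (both n = 2) and 0.517 ± 0.00460 in SPOCmut (n = 3). In CIZ1 KO it was 0.515 ± 0.00530 (n = 2). All genes measured start between 6.05 and 103.5 Mb, so the X beyond Xist is not covered. The plot of library medians sets these levels beside those after doxycycline.

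**Figure D1:**
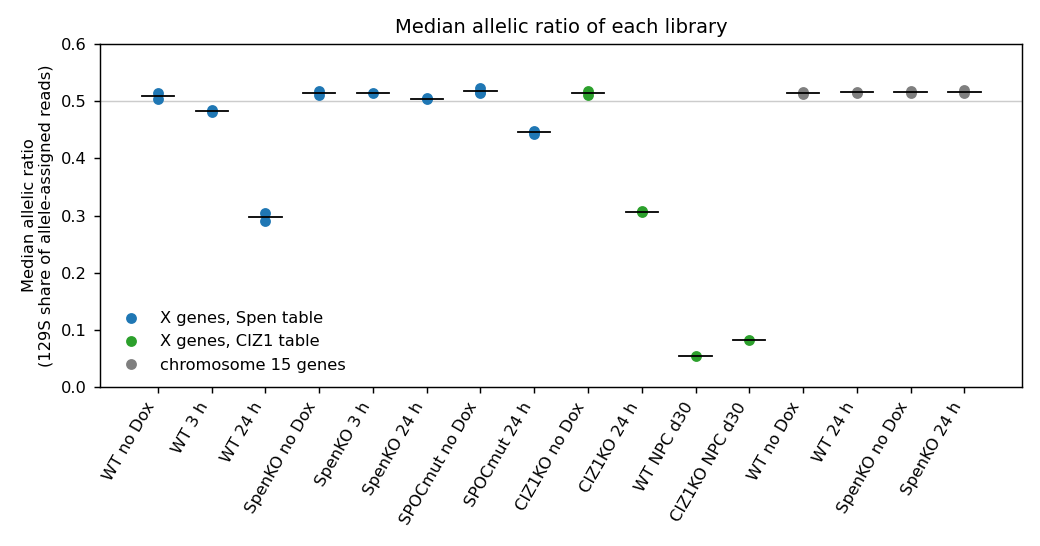
Each point is the median allelic ratio (129S share of allele-assigned reads, vertical axis from 0 to 0.6) of 1 library, by group along the horizontal axis, and black bars are group means. X genes lie near 0.5 without Dox, at 0.298 in WT (270 genes), 0.307 in CIZ1 KO (254 genes), 0.446 in SPOCmut and 0.504 in SpenKO at 24 h, and at 0.0546 and 0.0830 in the NPC libraries (1 library each), while the chromosome 15 libraries lie between 0.513 and 0.519.

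After 24 h of doxycycline, 240 of 270 X genes fell in WT cells and 0 rose in limma (243 and 0 at an unadjusted p under 0.05). The largest falls with non-overlapping replicates were those of Pja1, an E3 ubiquitin ligase, by 0.487 ± 0.110 (SE, adjusted p = 0.00163), and of Smarca1, an ISWI chromatin remodeller, by 0.456 ± 0.0589 (adjusted p = 2.66e-05). Firre (chromosome X, 50555743 to 50635258), a long noncoding RNA known to escape silencing in other cells, fell from 0.628 ± 0.00383 to 0.230 ± 0.00877 (n = 2 each, adjusted p = 1.49e-10). Nhsl2 fell from 0.442 to 0.0599, and L1cam, Msn and Slc7a3 fell by 0.372, 0.367 and 0.366. Kdm6a, a histone H3 lysine demethylase that escapes X inactivation, fell by only 0.0291 ± 0.00868 (adjusted p = 0.00871), from 0.556 to 0.526. The other least changed genes did not pass the test: Nudt10 changed by -0.00468 ± 0.0857, Zfp449 by 0.0101 ± 0.0474 and Srpx by -0.0389 ± 0.116. The median ratio was 0.298 ± 0.00968 against 0.509 ± 0.00661 without doxycycline (n = 2 each), with both treated libraries below both controls (exact permutation p = 0.333, the smallest possible).

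All 9 X-linked gene lists held mostly genes that fell at 24 h in WT. Of 26 chromatin and transcription regulators, 25 fell (25 adjusted over the list alone), among them Pola1, the catalytic subunit of DNA polymerase alpha, by 0.186 ± 0.00905 and the ETS factor Elf4 by 0.360 ± 0.0225. The exception was Suv39h1, a histone H3 lysine 9 methyltransferase, at -0.0449 ± 0.0304 (adjusted p = 0.178). Of 12 neural genes 12 fell (12 adjusted over the list alone), including Dmd, which encodes dystrophin, by 0.332 ± 0.0124. Of 20 genes of RNA processing and translation 19 fell (20 adjusted over the list alone), with Rbmx down by 0.274 ± 0.0175 and the translation initiation factor Eif2s3x by 0.0804 ± 0.0163. Of 26 metabolic and mitochondrial enzymes 21 fell (21 adjusted over the list alone), with Mtm1 down by 0.218 ± 0.0106 and the purine salvage enzyme Hprt by 0.152 ± 0.0172. The counts were 15 of 17 for pluripotency and early development (15 adjusted over the list alone), with the glypican Gpc3 down by 0.287 ± 0.0111. They were 10 of 12 for ubiquitin and proteolysis (10 adjusted over the list alone), with the deubiquitinase Usp9x down by 0.166 ± 0.00945. This was less than the list's median change of -0.221.

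Of 14 feeder fibroblast genes 13 fell at 24 h in WT (13 adjusted over the list alone), Flna, which encodes filamin A, by 0.276 ± 0.0137. Of 8 escape genes 7 fell (7 adjusted over the list alone), including the RNA helicase Ddx3x by 0.156 ± 0.0119 and Shroom4 by 0.175 ± 0.0163, and the eighth member was Xist itself. At the X inactivation centre, 3 of 4 genes fell (2 adjusted over the list alone): Tsix, the antisense partner of Xist, by 0.296 ± 0.0211, Chic1 by 0.257 ± 0.0150 and Nap1l2 by 0.226 ± 0.0957. No list differed from the other genes by camera (smallest adjusted p = 0.174 for each of the chromatin, neural and feeder lists). For the chromatin, escape, centre and RNA lists, the direction of camera was opposite to that of the list's median against the other genes.

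**Figure D2:**
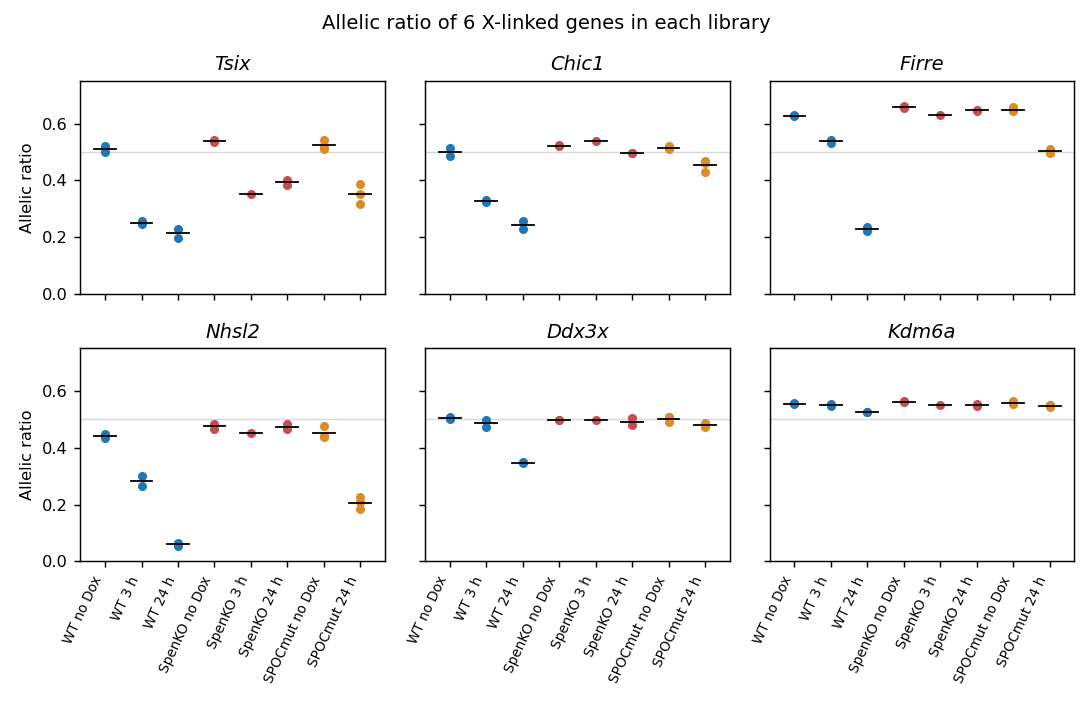
Allelic ratio (vertical axis, 0 to 0.75) of 6 X-linked genes in each library of WT (blue), SpenKO (red) and SPOCmut (orange), with black bars as group means. Firre is at 0.230 in WT, 0.647 in SpenKO and 0.504 in SPOCmut at 24 h, Tsix is at 0.251 in WT and 0.351 in the lone SpenKO library at 3 h, and Kdm6a stays between 0.526 and 0.562 in the group means.

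At 3 h of doxycycline, 46 X genes had fallen in WT and 14 had risen (67 and 25 at an unadjusted p under 0.05). The largest falls were those of the forkhead factor gene Foxo4, by 0.298 ± 0.0622 (adjusted p = 0.00577), and Tsix (chromosome X, 103431516 to 103484957), from 0.510 ± 0.0154 to 0.251 ± 0.00840 (adjusted p = 2.40e-05). Chic1 (103356475 to 103396118), next to Xist, fell by 0.172 ± 0.0150, the glycerol kinase gene Gyk by 0.186 ± 0.0175 and the amino acid transporter gene Slc7a3 by 0.173 ± 0.0312. Rises were those of Mamld1, by 0.452 ± 0.0633, the NADPH oxidase subunit gene Cybb, by 0.263 ± 0.0739, the sterol isomerase gene Ebp, by 0.199 ± 0.0316, Gabre, by 0.172 ± 0.0266, and Aff2, by 0.131 ± 0.0266. Tsix passed the threshold in all 14 settings tried. With only the libraries of this comparison in the fit, 2 genes passed, so the number of early calls rests on the spread taken from the other groups. With a minimum change of 0.1 the count was 31.

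Among the lists at 3 h, 7 of 26 chromatin regulators fell and 1 rose (9 adjusted over the list alone), with the O-GlcNAc transferase gene Ogt down by 0.0631 ± 0.0105 and Zmym3 by 0.130 ± 0.0298. Of 26 metabolic enzymes 5 fell and 3 rose (9 adjusted over the list alone). Of 17 pluripotency genes 5 fell (5 adjusted over the list alone), among them Tex11, by 0.128 ± 0.0230, and Mageb16 and Xlr3a, members of multigene families whose reads may be shared between copies. Of 20 RNA processing genes 4 fell (4 adjusted over the list alone), including the ribosomal protein gene Rps4x by 0.0588 ± 0.0118. Of 14 feeder fibroblast genes 4 fell and 1 rose (6 adjusted over the list alone), and of 12 neural genes 2 fell and 1 rose (3 adjusted over the list alone). Of 12 ubiquitin genes 2 fell (3 adjusted over the list alone), and of 8 escape genes Firre fell, by 0.0912 ± 0.00971, while Shroom4 and 1810030O07Rik rose (3 adjusted over the list alone). At the centre 2 of 4 fell, Tsix and Chic1 (2 adjusted over the list alone), and no list passed by camera, the centre coming closest at an adjusted p of 0.366.

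From 3 h to 24 h, 231 genes fell and 1 rose in WT. Mamld1 fell by 0.670 ± 0.0633 between these times, Elf4 by 0.456 ± 0.0225, Timp1 by 0.449 ± 0.0702 and Msn by 0.406 ± 0.0216. Tsix did not pass, at -0.0370 ± 0.0211 (adjusted p = 0.123). The gene that rose was Slc25a5, an ADP/ATP translocase gene, by 0.143 ± 0.0473 (adjusted p = 0.0152). The median ratio went from 0.483 ± 0.00228 at 3 h to 0.298 ± 0.00968 at 24 h (n = 2 each, exact permutation p = 0.333, the smallest possible).

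At 3 h in WT the change varied along the X. The median change was -0.0986 in the 25 genes from 100 Mb to Xist, where 16 fell, -0.0337 in the 76 genes from 60 to 80 Mb, where 16 fell too, and 0.0294 in the 54 genes of the first 20 Mb, where 7 rose and 0 fell in limma (12 and 3 at an unadjusted p under 0.05). The Spearman correlation of the change with distance to Xist over 269 genes was 0.538 (permutation p = 1e-05, the smallest the permutations can give; adjusted 1.67e-05). At 24 h it was 0.305 in WT and 0.304 in SPOCmut (adjusted p = 1.67e-05 for both), 0.219 over 253 genes in CIZ1 KO (adjusted p = 0.000638) and 0.00430 in SpenKO (adjusted p = 0.944). Without genes before 13 Mb, the correlation for WT at 3 h was 0.439. At 24 h it was then 0.229 in WT, 0.218 in CIZ1 KO, 0.255 in SPOCmut and 0.0565 in SpenKO. WT and CIZ1 KO thus differed little beyond 13 Mb. These values without the first 13 Mb were not tested. At 24 h in WT, genes fell along the whole measured X, from 41 of 54 in the first 20 Mb, with a median change of -0.156, to 24 of 25 nearest Xist, with a median change of -0.257. These correlations run over genes, which are not independent replicates.

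**Figure D3:**
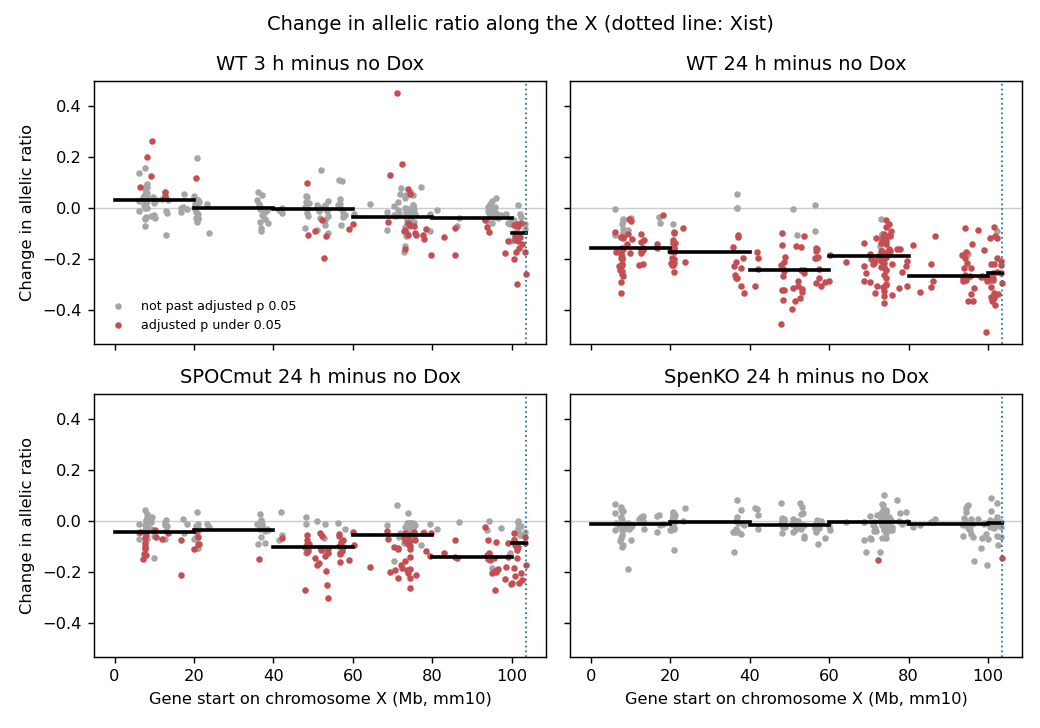
Change in allelic ratio (Dox minus no Dox, vertical axis) of each X gene by its start in Mb (mm10), for WT at 3 h and for WT, SPOCmut and SpenKO at 24 h. Red points passed the adjusted p of 0.05, black lines are medians of 20 Mb bins and the dotted line marks Xist, and the WT 3 h medians run from 0.0294 in the first bin to -0.0986 in the last.

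In CIZ1 KO cells, whether silencing needs CIZ1 was addressed by the same induction. After 24 h, 216 of 254 genes fell and 0 rose in limma (219 and 0 at an unadjusted p under 0.05). Ccdc160 fell by 0.546 ± 0.106, Smarca1 from 0.547 to 0.0208 (by 0.526 ± 0.0259, adjusted p = 7.72e-05), Zmym3 by 0.464 ± 0.0405 and the interleukin receptor gene Il13ra1 by 0.441 ± 0.0946. Firre fell by 0.392 ± 0.0152, Tsix by 0.301 ± 0.0177 and Kdm6a by 0.0413 ± 0.0138 (adjusted p = 0.0313). The median ratio was 0.307 ± 0.000883 against 0.515 ± 0.00530 without doxycycline (n = 2 each, exact permutation p = 0.333, the smallest possible).

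By list, 25 of 26 chromatin regulators fell in CIZ1 KO, as did 20 of 20 RNA processing genes, 10 of 10 ubiquitin genes and 23 of 25 metabolic enzymes. The counts were 12 of 13 for pluripotency genes, 11 of 13 for neural genes, 13 of 14 for feeder fibroblast genes, 7 of 8 for escape genes and 3 of 4 at the centre. Each of these 9 counts was the same when adjusted over the list alone. Klhl15, a substrate adaptor of a ubiquitin ligase, fell by 0.363 ± 0.0163, Pdk3 by 0.313 ± 0.0169 and Med12, a Mediator subunit gene, by 0.313 ± 0.0229. The neural gene Il1rapl1, at -0.00159 ± 0.0381, and Suv39h1, at -0.0348 ± 0.0236, did not pass. No list passed by camera (smallest adjusted p = 0.357).

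CIZ1 KO and WT did not differ in any gene at 24 h in limma (0 lower and 0 higher; 4 and 21 at an unadjusted p under 0.05, smallest adjusted p = 0.0692). Over the same 254 genes the median ratio at 24 h was 0.307 ± 0.000883 in CIZ1 KO and 0.293 ± 0.00587 in WT (n = 2 each), a difference of 0.0140, with both CIZ1 KO libraries above both WT libraries (exact permutation p = 0.333, the smallest possible). With the other summaries over genes this difference ran from 0.00643 to 0.0164. Without doxycycline the difference of the medians was 0.00551. At 24 h Firre was at 0.254 ± 0.0102 in CIZ1 KO and 0.230 ± 0.00877 in WT, and Tsix at 0.229 ± 0.000193 and 0.214 ± 0.0219 (n = 2 each). Over genes, the 2 CIZ1 KO libraries without doxycycline correlated by 0.745, against 0.847 to 0.905 in the other replicate pairs of this table. The spread of a gene is shared over groups, so this pair also enters the intervals at 24 h. For CIZ1 KO against WT at 24 h, the median 95% interval of a gene's difference was ± 0.0680 wide. In simulated data for this comparison 23.3% of changes of 0.05 and 57.4% of changes of 0.1 were recovered, so differences of these sizes can be missed. In these simulations 40 genes changed by each size, and with few true differences the shares recovered would be lower. Without doxycycline 0 genes differed (4 lower and 12 higher at an unadjusted p under 0.05), and 4 did when replicate 1 of CIZ1 KO without doxycycline was left out. The 24 h response itself differed between the lines in 0 genes of 254 (4 and 7 at an unadjusted p under 0.05), in 2 without that same library, and in 0 members of each of the 9 lists (0 adjusted over the list alone; at an unadjusted p under 0.05, 1 metabolic, 1 RNA processing and 1 ubiquitin gene). For Tsix the difference of responses, CIZ1 KO minus WT, was -0.00442 ± 0.0250, for Firre 0.00720 ± 0.0215 and for Klhl15 -0.0987 ± 0.0230 (adjusted p = 0.477).

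In SpenKO cells, 2 of 270 genes fell at 24 h and 0 rose in limma (18 and 1 at an unadjusted p under 0.05). Tsix fell from 0.539 ± 0.00600 to 0.394 ± 0.0125 (n = 2 each, by 0.145 ± 0.0211, adjusted p = 0.00900). Gabre, a GABA receptor subunit gene, fell from 0.510 ± 0.0248 to 0.358 ± 0.00562 (by 0.152 ± 0.0266, adjusted p = 0.0212). Firre was at 0.658 ± 0.00514 without and 0.647 ± 0.00285 with doxycycline, Chic1 at 0.521 and 0.496, and Ddx3x at 0.498 and 0.492. The median ratio was 0.504 ± 0.00173 after 24 h and 0.515 ± 0.00505 before (n = 2 each, exact permutation p = 0.333, the smallest possible). Both treated libraries lay below both untreated ones. Changes were below 0, at any size, in 182 of 270 X genes, against 238 of 458 chromosome 15 genes in SpenKO. These 2 shares were not tested against each other, so a small remaining shift on the X stays possible. Both calls were lost, leaving 0 genes, with only the libraries of this comparison in the fit, with Benjamini-Yekutieli adjustment, and without SpenKO 24 h replicate 1, SpenKO 24 h replicate 2 or SpenKO no-doxycycline replicate 2.

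No member of 8 of the X lists passed in SpenKO at 24 h, and at the centre 1 of 4 did, Tsix (1 adjusted over the list alone). Adjusted over the list alone, 2 neural genes passed and 0 genes of the others did in limma (at an unadjusted p under 0.05, 3 feeder fibroblast genes, 1 chromatin regulator, 1 metabolic enzyme and Xist). Over all genes the neural gene Aff2 stood at -0.121 ± 0.0266 (adjusted p = 0.0834) and Phka1, a phosphorylase kinase subunit gene of the metabolic list, at -0.0943 ± 0.0265 (0.202). No list passed by camera (smallest adjusted p = 0.249, feeder fibroblast genes). Of the pluripotency, RNA processing and ubiquitin lists, the median change was below 0 and the mean change above 0. The same held for the escape list with Xist, but without it both were below 0 (-0.00560 and -0.00290).

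The 24 h response differed between SpenKO and WT in 207 genes, all with the smaller fall in SpenKO and 0 the other way in limma (209 and 0 at an unadjusted p under 0.05). The difference was 0.528 ± 0.0833 for Smarca1, 0.474 ± 0.115 for L1cam, 0.436 ± 0.155 for Pja1, 0.422 ± 0.0798 for Kis2 and 0.388 ± 0.0137 for Firre. It was 0.151 ± 0.0299 for Tsix (adjusted p = 0.000924), and it did not pass for Kdm6a (0.0173 ± 0.0123, adjusted p = 0.210). It passed in 23 of 26 chromatin regulators, 12 of 12 neural genes, 19 of 20 RNA processing genes, 15 of 17 pluripotency genes and 17 of 26 metabolic enzymes. It also passed in 12 of 14 feeder fibroblast genes, 10 of 12 ubiquitin genes, 6 of 8 escape genes and 2 of 4 genes at the centre, each count being the same adjusted over the list alone. No list stood apart by camera (smallest adjusted p = 0.245). Compared directly at 24 h, 238 genes were higher in SpenKO than in WT and 0 lower in limma (240 and 0 at an unadjusted p under 0.05), Nhsl2 by 0.415 ± 0.0179.

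At 3 h the lone SpenKO library had a median ratio of 0.515, and its median gene changed by -0.000564 against -0.0205 in WT. In that library Tsix was at 0.351 against 0.539 without doxycycline, Nap1l2 at 0.0986 against 0.301 and Srpx at 0.188 against 0.502. Cybb was at 0.945 against 0.556 and Dusp9, a phosphatase gene, at 0.783 against 0.546. This library has no spread of its own. A limma test that assumes it varies like the others called 7 genes for the 3 h response against WT, all higher in SpenKO and 0 lower (40 and 10 at an unadjusted p under 0.05), but 0 genes with only these groups in the fit. A difference at 3 h is therefore not shown without that assumption. Under it, the genes called included Slc7a3, by 0.232 ± 0.0493 (adjusted p = 0.0326), Chic1, by 0.191 ± 0.0237 (0.00157), Gyk, by 0.152 ± 0.0277 (0.0153), and Stard8, by 0.132 ± 0.0171 (0.00157). Tsix did not pass (0.0709 ± 0.0334, adjusted p = 0.273). The count was 4 on the logit scale, 2 without SpenKO no-doxycycline replicate 1, 2 without WT no-doxycycline replicate 1, 4 without WT no-doxycycline replicate 2 and 2 with Benjamini-Yekutieli adjustment.

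In SPOCmut cells 134 of 270 genes fell at 24 h and 0 rose in limma (148 and 1 at an unadjusted p under 0.05). The largest falls were those of AW822252, by 0.301 ± 0.0634, Zc4h2, by 0.272 ± 0.0485, Smarca1, by 0.271 ± 0.0481, and Fam3a, by 0.263 ± 0.0506. Nhsl2 fell from 0.452 ± 0.0211 to 0.207 ± 0.0205 and the ectodysplasin gene Eda from 0.480 ± 0.00177 to 0.236 ± 0.0193 (n = 3 each). Firre fell by 0.145 ± 0.00793 and Tsix by 0.172 ± 0.0173 (adjusted p = 1.39e-05), while Kdm6a, at -0.0100 ± 0.00709, Ddx3x, at -0.0212 ± 0.00969, and Hprt, at -0.0104 ± 0.0140, did not pass. The median ratio was 0.446 ± 0.00296 against 0.517 ± 0.00460 (n = 3 each), with all 3 treated clones below all 3 controls (exact permutation p = 0.1, the smallest possible). Of the 134 falls, 79 were of at least 0.1.

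Of 14 feeder fibroblast genes, 11 fell in SPOCmut (11 adjusted over the list alone), including Cd99l2 by 0.226 ± 0.020, Pls3, which encodes the actin bundling protein plastin 3, by 0.214 ± 0.0192, Fhl1 by 0.163 ± 0.0145 and Flna by 0.143 ± 0.0112. Their median change was -0.144 against -0.0633 in the other genes, an adjusted p of 0.0112 by camera, and the adjusted p = 0.183 with an estimated correlation. The excess was not particular to SPOCmut. At 24 h the list's median was -0.279 against -0.195 in the other genes in WT and -0.292 against -0.203 in CIZ1 KO. In SpenKO it was -0.0295 against -0.00791. The difference of responses, SPOCmut minus WT, had a list median of 0.128 against 0.120 (adjusted p = 0.491 by camera). Of 12 neural genes 8 fell (8 adjusted over the list alone), with Dmd down by 0.127 ± 0.0101, and of 26 chromatin regulators 14 fell (14 adjusted over the list alone), with the deacetylase gene Hdac8 down by 0.205 ± 0.0171. The counts were 12 of 26 metabolic enzymes (12 adjusted over the list alone), with Phka1 down by 0.232 ± 0.0216, and 8 of 17 pluripotency genes (8 adjusted over the list alone), with Tex11 down by 0.215 ± 0.0188. They were 8 of 20 RNA processing genes (8 adjusted over the list alone), 2 of 12 ubiquitin genes (2 adjusted over the list alone), Klhl15 and Tab3, and 2 of 8 escape genes (2 adjusted over the list alone), Firre and Shroom4. At the centre 2 of 4 fell, Tsix and Chic1 (2 adjusted over the list alone), and no list but the feeder fibroblast one passed by camera.

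The response of SPOCmut was weaker than that of WT in 158 genes and stronger in 0 in limma (170 and 0 at an unadjusted p under 0.05). The difference, SPOCmut minus WT, was 0.361 ± 0.142 for Pja1, 0.316 ± 0.0192 for Pdzd4, 0.297 ± 0.0518 for the cullin gene Cul4b and 0.297 ± 0.0490 for Itgb1bp2. For Firre it was 0.254 ± 0.0125, for Tsix 0.124 ± 0.0273 and for Usp9x 0.168 ± 0.0122. It passed in 21 of 26 chromatin regulators (21 adjusted over the list alone), with a median of 0.135 against 0.120 in the other genes. This list had an adjusted p of 0.0355 by camera, with an adjusted p = 0.151 with an estimated correlation and 0.0657 with the filter on no-doxycycline means. The counts were 10 of 12 neural genes (10 adjusted over the list alone), 15 of 20 RNA processing genes (15), 10 of 12 ubiquitin genes (10), 13 of 17 pluripotency genes (13), 10 of 14 feeder fibroblast genes (11), 13 of 26 metabolic enzymes (12), 6 of 8 escape genes (6) and 2 of 4 at the centre (2), each with the count adjusted over the list alone in parentheses. Compared directly at 24 h, 213 genes were higher in SPOCmut than in WT and 1 was lower, Slc25a5, by -0.130 ± 0.0432 (adjusted p = 0.0176). Its no-doxycycline ratio was 0.387 ± 0.0194 in SPOCmut and 0.467 ± 0.00543 in WT.

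The response of SPOCmut was stronger than that of SpenKO in 62 genes and weaker in 0 in limma (100 and 0 at an unadjusted p under 0.05). The difference, SPOCmut minus SpenKO, was -0.343 ± 0.0761 for Smarca1, -0.284 ± 0.0487 for Mospd1, -0.279 ± 0.0766 for Zc4h2, -0.258 ± 0.0800 for Fam3a, -0.244 ± 0.0231 for Nhsl2 and -0.231 ± 0.0505 for Plxna3. For Tsix it was -0.0267 ± 0.0273 (adjusted p = 0.566). Compared directly at 24 h, 110 genes were higher in SpenKO and 3 lower, with Nhsl2 higher by 0.268 ± 0.0164 and Cybb, Eras and F8 lower by -0.372 ± 0.0675, -0.227 ± 0.0755 and -0.0771 ± 0.0250. Without SpenKO 24 h replicate 1 the first count was 41, and with Benjamini-Yekutieli adjustment it was 34. The medians of the 2 SpenKO libraries lay above those of the 3 SPOCmut libraries (0.504 against 0.446, exact permutation p = 0.2, the smallest possible).

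NPC at day 30 were represented by 1 library per genotype, so their differences have no replicate check and were not tested. The median ratio of X genes was 0.0546 in WT and 0.0830 in CIZ1 KO, and 163 and 145 of 254 genes lay below 0.1. With a limit of 0.05 the counts were 119 and 90, and with a limit of 0.2 the order turned, at 210 and 212. Above 0.3 lay 19 genes in WT and 12 in CIZ1 KO. Kdm6a was at 0.390 in WT and 0.405 in CIZ1 KO, Eif2s3x at 0.236 and 0.326, Ddx3x at 0.203 and 0.224, and Firre at 0.156 and 0.180. The 6 genes with the largest excess in WT all start below 9 Mb and include Wdr13 (0.354 against 0.107), the Wnt acyltransferase gene Porcn (0.316 against 0.0833), Glod5 (0.400 against 0.182) and Nudt10 (0.200 against a listed 0). Higher in CIZ1 KO were Pin4 (0.385 against 0.104), Mir669m-2 (0.423 against 0.148), Nkap (0.323 against 0.150), Igbp1 (0.192 against 0.0293) and the monoamine oxidase gene Maob (0.200 against 0.0417).

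Along the X, the WT library lay above the CIZ1 KO library in 39 of 54 genes of the first 20 Mb, with a median difference, CIZ1 KO minus WT, of -0.0759. In each of the other bins CIZ1 KO was higher in most genes that differed, with medians from 0.0114 to 0.0269. Of the lists, escape genes other than Xist (n = 7) had the high medians of 0.236 in WT and 0.290 in CIZ1 KO. These lay at the 99.3 percentile of 10000 random lists in WT and above all of them in CIZ1 KO. The random lists were not matched on position, and Shroom4, 1810030O07Rik, Ddx3x and Kdm6a of the escape list start in the first 20 Mb. The median there was 0.203 in WT, against 0.0138 to 0.0976 in the other bins. In CIZ1 KO it was 0.118, against 0.0338 to 0.1225. RNA processing genes were at 0.154 and 0.206 (percentile 99.7 in WT and above all random lists in CIZ1 KO) and chromatin regulators at 0.0857 and 0.133 (87.4 and 99.2). These lists share 3 genes (Ddx3x, Eif2s3x and Utp14a) and 1 gene (Kdm6a) with the escape list. Without them, a setting added after the data were seen, RNA processing genes were at 0.116 and 0.154 (96.3 and 98.7) and chromatin regulators at 0.0845 and 0.129 (84.4 and 98.4). Ubiquitin genes were at 0.0669 and 0.121 (59.8 and 86.2) and metabolic enzymes at 0.0417 and 0.101 (23.7 and 78.4). Pluripotency genes were at 0.0268 and 0.0404 (8.28 and 6.31), neural genes at 0.0235 and 0.0649 (3.55 and 28.3), feeder fibroblast genes at 0.0318 and 0.0369 (13.1 and 3.73) and genes of the centre at 0.0197 and 0.0198 (16.9 and 9.28).

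**Figure D4:**
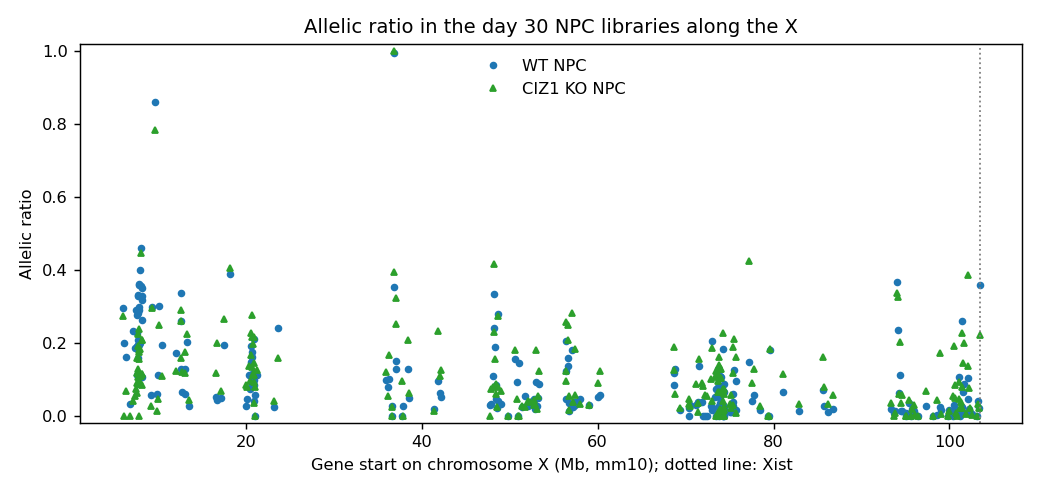
Allelic ratio (vertical axis, 0 to 1) of each X gene except Xist in the day 30 NPC library of WT (blue circles) and of CIZ1 KO (green triangles), by gene start in Mb (mm10), with 1 library per genotype. In the first 20 Mb the medians are 0.203 in WT and 0.118 in CIZ1 KO, and from 60 to 80 Mb they are 0.0355 and 0.0663.

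Chromosome 15 served as an autosome without inducible Xist in the same lines. In WT the median ratio of its 458 genes was 0.516 ± 0.00132 at 24 h and 0.514 ± 0.00182 without doxycycline, and in SpenKO 0.517 ± 0.00316 and 0.516 ± 0.00268 (n = 2 each, exact permutation p = 0.667 for both). No gene changed in WT in limma (0 lower and 0 higher; 9 and 9 at an unadjusted p under 0.05), in SpenKO (0 and 0; 11 and 13) or between SpenKO and WT without doxycycline (0 and 0; 17 and 18). The cohesin gene Rad21 stood at 0.00823 ± 0.0151 in WT and -0.0158 ± 0.0151 in SpenKO, Ep300, a histone acetyltransferase gene, at -0.00133 ± 0.0154 and -0.0114 ± 0.0154, and Rpl3 at -0.000494 ± 0.0167 and -0.0136 ± 0.0167.

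In each of the 5 chromosome 15 lists 0 genes passed in WT and SpenKO in limma (0 adjusted over the list alone; at an unadjusted p under 0.05, up to 4 genes of a list in WT and up to 3 in SpenKO). These were 42 chromatin regulators, 36 RNA processing genes, 35 mitochondrial and metabolic enzymes, 36 genes of cell cycle, cytoskeleton and DNA repair, and 19 feeder fibroblast genes. By camera the metabolic list was shifted up in WT, with a median of 0.0133 against -0.000103 in the other genes and an adjusted p of 0.0269, and the adjusted p = 0.163 with an estimated correlation. Its members with the smallest p, Gcat at 0.0840 ± 0.0260 and Pim3 at 0.0503 ± 0.0182, did not pass singly (adjusted p = 0.933 for both). No chromosome 15 list passed in SpenKO.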

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

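The tests of the differences between lines were planned, while the splits of the SPOCmut libraries and the relation of the SPOCmut share with distance to Xist were tests chosen only after the results were seen. The correlation with distance in SpenKO was planned, and was taken up here after its value was seen. The responses to doxycycline of 2 lines were compared directly, by an interaction contrast in limma, and those called are listed here. Between SpenKO and WT at 24 h, 207 genes differed, with the largest differences, SpenKO minus WT, at 0.528 for Smarca1, 0.474 for L1cam, 0.436 for Pja1, 0.422 for Kis2, 0.388 for Firre and 0.385 for C430049B03Rik. Between SPOCmut and WT, 158 genes differed, with 0.361 for Pja1, 0.316 for Pdzd4, 0.297 for Cul4b, 0.297 for Itgb1bp2, 0.295 for Gm7173 and 0.288 for Kis2. Between SPOCmut and SpenKO, 62 genes differed, with -0.343 for Smarca1, -0.284 for Mospd1, -0.279 for Zc4h2, -0.258 for Fam3a, -0.244 for Nhsl2 and -0.231 for Plxna3 (41 genes without SpenKO 24 h replicate 1). At 3 h, where SpenKO has 1 library that is assumed to vary like the other groups, 7 genes were called between SpenKO and WT, with 0.232 for Slc7a3, 0.191 for Chic1, 0.152 for Gyk, 0.137 for Nsdhl, 0.137 for Nhsl2 and 0.132 for Stard8. With only these groups in the fit the last count was 0 in limma, so these genes are not shown to differ without that assumption. It was 2 with Benjamini-Yekutieli adjustment. Without SpenKO no-doxycycline replicate 1 it was 2, without WT no-doxycycline replicate 1 it was 2, and without WT no-doxycycline replicate 2 it was 4.

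The 134 genes that fell in SPOCmut were set against the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 gave as many genes, the real one, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached. Each of the other splits also mixes treated and untreated libraries on both sides. A change after doxycycline then enters the spread within sides and shrinks the contrast, so low counts there were to be foreseen. The replicate numbers pair these libraries by clone. The real split parts all 3 pairs, and the other splits that do so gave 0 genes, as did those that keep a pair on one side.

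Of the 240 genes that fell in WT at 24 h, 132 also fell in SPOCmut and 108 did not pass there. The change in SPOCmut was 34.7% of that in WT in the median gene (quartiles 17.6% and 54.9%). This share fell with distance to Xist over these genes (Spearman rho = -0.176, permutation p = 0.00646). By 20 Mb bin its median was 30.8%, 19.1%, 37.8%, 35.7% and 51.6% from the start of the X to 100 Mb, and 34.8% from there to Xist. In SpenKO the 24 h change itself showed a rho of 0.00430 with distance (permutation p = 0.944), and median changes by bin lay between -0.0141 and -0.00282.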

How the results depend on the processing

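Apart from 5 alternatives chosen after seeing the data, all settings here were planned. Where leaving out a library leaves a group of 1, that library is assumed to vary like the other groups. Over these settings, 93 of the counts with a library left out and 141 of the other counts stayed within 1.5 times the reported one, 7 and 14 fell further, and 2 rose from 0. No named gene changed direction past the threshold: for the genes named, 3249 values with a library left out and 4777 others kept their side of the threshold, 159 and 185 lost it, and 18 and 21 gained it. The counts for WT at 24 h (240) ran from 206 to 243, and from 217 to 230 with a library left out, and those for CIZ1 KO (216) from 178 to 218. The counts for CIZ1 KO against WT at 24 h, and for chromosome 15, were 0 in all settings.

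With only the groups compared in the fit, the count fell from 60 to 2 for WT at 3 h, from 2 to 0 for SpenKO at 24 h and from 7 to 0 for the 3 h difference between SpenKO and WT. Such a fit holds fewer libraries to estimate the spread. A minimum change of 0.1 left 31 genes for WT at 3 h, 79 of 134 for SPOCmut and 60 of 113 for SpenKO against SPOCmut at 24 h. Benjamini-Yekutieli adjustment left 38 for WT at 3 h, 0 for SpenKO, 67 for SpenKO against SPOCmut, 34 of 62 for the difference between SPOCmut and SpenKO and 2 of 7 for the 3 h difference. The logit scale left 4 of these 7, for which the cause was not tested. The leave-out ranges were 0 to 4 for CIZ1 KO against WT without doxycycline (4 without CIZ1 KO no-doxycycline replicate 1) and 0 to 2 for the difference of their responses (2 without that library). They were 0 to 3 for SpenKO (0 without either 24 h library or without no-doxycycline replicate 2), 41 to 58 for SPOCmut minus SpenKO (41 without SpenKO 24 h replicate 1) and 2 to 7 for the 3 h difference.

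The replicate number as a block left 53 genes for WT at 3 h, 237 for WT, 218 for CIZ1 KO, 0 for SpenKO and 135 for SPOCmut at 24 h, and 3 of 7 for the 3 h difference. For SPOCmut, whose numbers stand for clones, the block changed no count by more than 1.5 times, and no call of a gene named for its 24 h comparison. The other lines share only a number, and deviations of same-numbered libraries at 24 h and without doxycycline correlated by 0.101 in WT, 0.112 in SpenKO and -0.107 in CIZ1 KO.

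The median over chromosome 15 genes in SpenKO, which differed by 0.000461, turned to -0.00107 as a mean, to -0.00164 relative to the no-doxycycline mean, and ran from -0.00177 (without 24 h replicate 2) to 0.00269 with a library left out, including -0.00144 without no-doxycycline replicate 2. The difference between the bin at Xist and the first bin for WT at 24 h was -0.101 in 20 Mb bins and -0.0958 in 10 Mb bins, and for the NPC libraries 0.0972 and 0.139, the last chosen after seeing the data. With a limit of 0.05, 90 CIZ1 KO genes of the NPC library lay below it, against 145 below 0.1 and 212 below 0.2. Of the gene lists, 159 of the alternative tests kept their side, 4 lost it and 1 gained it: with the filter on no-doxycycline means, the X inactivation centre passed at 3 h in WT (adjusted p = 0.0484), against 0.366 without the filter and 0.598 with an estimated correlation. The filter takes Xist out of this list of 4 genes.

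The value relative to the no-doxycycline mean cannot be formed between groups without doxycycline. The planned comparison of the chromosome 15 transgene line was not run, since its samples have no column. The depth is unknown, so no limit from counting error can be given.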

Other observations

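The correlations between lines, the change point scan and the tests of the explanations weighed in this part were chosen only after the results were seen. At 24 h, among genes with a no-doxycycline mean from 0.2 to 0.8, the median gene was at 60.3% of its no-doxycycline ratio in WT, 58.9% in CIZ1 KO, 86.8% in SPOCmut and 97.9% in SpenKO, against 95.9% in WT at 3 h. The sets of genes differ: 259 genes of the Spen table in WT and 245 of the CIZ1 table in CIZ1 KO. The order of these 2 lines is therefore no sign of deeper silencing in CIZ1 KO. Within the CIZ1 table, the other summaries put CIZ1 KO above WT at 24 h by 0.00643 to 0.0164. They include the summary relative to the no-doxycycline mean. The chromosome 15 genes were at 100.2% in WT and 99.8% in SpenKO. Between WT and CIZ1 KO the 24 h changes of 247 genes correlated with a Spearman rho of 0.767 and a Pearson r of 0.760, and 205 genes fell in both, where 194.9 are expected of independent lists. Between WT and SPOCmut at 24 h rho was 0.582 and r 0.567, and 132 genes fell in both against 119.6 expected. For rho the permutation p was 1e-05 in both pairs, the smallest the permutations can give. For 37 of the 46 genes that fell at 3 h in WT, a fall at 24 h was found in SPOCmut too (22.9 expected, rho 0.179, permutation p = 0.00312), and for 43 of the 45 in both tables a fall in CIZ1 KO at 24 h (38.8 expected, rho 0.189, permutation p = 0.00269). Between SPOCmut and SpenKO rho was 0.223 (permutation p = 0.00025), with 2 genes lower in both against 0.996 expected. These 5 relations run over genes, which are not independent replicates, and between comparisons that share no library. All 5 rho values had adjusted permutation p-values at or below 0.00312. The overlap counts were not tested. Calls of 1 fit share a residual spread per gene, which the expected counts ignore.

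A few genes stood at one end of the scale in all libraries of a table, with or without doxycycline, and were named after their values were seen. Ube2a, a ubiquitin-conjugating enzyme gene (chromosome X, 36874365 to 36884220, mm10), was at 1 in all 17 libraries of the Spen table, and its neighbour C330007P06Rik (36848543 to 36864246) was between 0.998 and 1. Frmd7 (50892644 to 50942710) was between 0 and 0.0290 in the same libraries, and no more than 0.0230 in the 10 libraries of the CIZ1 table. On chromosome 15, the cadherin gene Cdh18 lay between 0.978 and 1 and the syntrophin gene Sntb1 between 0.949 and 0.976 in all 8 libraries.

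The 14 genes that rose at 3 h in WT had a median change of 0.106. A shift of the first 13 Mb of the X alone is argued against, since 7 of the 14 genes start there and the others do not. The rises were still frequent in that block, which holds 45 of the measured genes against 224 beyond it without Xist. Its median change was 0.0362, against -0.0279 beyond it. Noise of thinly covered genes stays open, as the depth is unknown. With only the libraries of this comparison in the fit 1 of the 14 passed. That fit took all calls, falls included, from 60 to 2, so it cannot decide. The 24 h comparison of SpenKO called 0 genes higher in limma (1 at an unadjusted p under 0.05). A shift shared by the 3 h libraries of WT and SpenKO is a candidate explanation. The same genes had a median change of 0.0253 in the lone SpenKO 3 h library, above 97.8% of random gene sets. Of the 14, 11 were higher there. The random sets were not matched on position. In that library the first 13 Mb had a median change of 0.0148, against -0.00188 beyond, so position alone could give such a percentile. Whether such a shift comes from the treatment or from the handling of the 3 h libraries stays open, as the labels give no batch.

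Tsix, whose span covers all of Xist, fell in SpenKO at 24 h, as did Gabre, while 268 genes did not pass. Xist reads counted for Tsix would raise the Tsix ratio towards that of Xist, but it fell by 0.145, against a spread between replicates of 0.00981. Scatter between libraries stays open: the highest treated library, including the 3 h one, lay at -0.132 from the lowest untreated one, but Tsix was taken up here for its call. That call was lost with only the libraries of this comparison in the fit (adjusted p = 0.143), with Benjamini-Yekutieli adjustment (0.0556), and without SpenKO 24 h replicate 1 (adjusted p = 0.0600), SpenKO 24 h replicate 2 (0.148) or SpenKO no-doxycycline replicate 2 (0.0835), over a range from 0.00866 to 0.148 in all alternatives. No biological explanation was tested.

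In the NPC libraries a scan for 1 change point placed it between genes starting at 12587758 and 12654883 on the X. The 42 genes before it had a median difference, CIZ1 KO minus WT, of -0.105 and the 211 after it one of 0.0208. Such a scan always places a point, and no p is given for a difference between 2 single libraries. A share of cells with an unsilenced X in the WT culture is argued against, since beyond 13 Mb the median difference was 0.0201, with CIZ1 KO higher in 146 of 208 genes. Of the 42 genes before the change point, 39 were higher in WT, so a change of the whole block in one culture (such as a gain, a loss or a recombination) could account for it, and with 1 library per genotype this cannot be told apart from an effect of CIZ1. In ES cells at 24 h the medians of these first 13 Mb were 0.313 in WT and 0.313 in CIZ1 KO. The NPC change point took 45.4% of the variance over genes. For the difference of 24 h responses, CIZ1 KO minus WT, the scan took 2.33% (permutation p = 0.268). For WT at 3 h it took 20.1% (permutation p = 1e-05), between genes starting at 72257431 and 72913564. Medians there were 0.00493 before and -0.0579 after. For the lone SpenKO 3 h library it took 4.13%. These permutations treat genes as independent.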
